A study of Synechocystis sp. PCC 6803 with 6 samples.

How the data were processed

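RNA of 6 samples of the unicellular cyanobacterium Synechocystis was measured on a spotted array that carried 2 spots for each of 3074 genes. Per the labels, 3 samples came from the glucose-tolerant wild type (GT) and 3 from an ntcA-overexpressing strain (NOX10), described as independent strains of each kind. The labels do not mention separate cultures, so p-values measure only the spread between these samples, which may be technical. Growth was nitrogen-replete, with 5 mM NH4Cl and light of 50 to 70 µmol photons per square metre and second. The labels give Cy3 for all 3 GT samples and Cy5 for all 3 NOX10 samples, so dye and strain cannot be told apart in any comparison.

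The deposited files held 1 intensity per spot, per the file headers, on a linear scale and without a background column or quality flag. Scanner, image software and background handling are not given in the sources used here. A deposited table of the whole series held the same intensity values, with 0 differences. The authors' value table held 1 intensity per gene and sample. Set against the spot files, it was found to be the mean of both spots after each was scaled to a common mean of 3253, to within 3.14 intensity units. It is linear and uncentred, with column medians of 2359, 1746 and 1709 for GT replicates 1 to 3 and 2105, 1740 and 1636 for NOX10 replicates 1 to 3. It served as an alternative.

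All spot intensities of the 6 samples were quantile-normalized together, converted to log2 and averaged over the 2 spots of a gene. No floor was needed, since 0 values lay at or under 0. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, strain as the only term), with Benjamini-Hochberg adjustment over 3074 genes and a threshold of 0.05. Standard errors and 95% confidence intervals are those of limma. Fold changes are NOX10 over GT. Arrays give no counting depth, so the number of samples limits the precision.

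Replicate numbers are shared by both strains in the labels, which do not say what a number stands for. Deviations from the strain means correlated across genes at 0.827, 0.782 and 0.879 in the same-numbered pairs, against -0.749 to 0.438 in the other combinations. Deviations within a strain cancel out by construction and replicate 1 stood apart, so the values that involve replicate 1 say little about pairing. Between replicates 2 and 3 the other combinations gave 0.394 and 0.438. Log2 differences between the first and second spot of a gene, which carry position rather than RNA, correlated at 0.519, 0.947 and 0.967 in the same-numbered pairs and at 0.387 or less elsewhere. The numbers were therefore taken to pair the samples, and same-numbered samples to share 1 array. A fit with the replicate number as a block, called the paired fit, is given beside each result whose call it changes. It leaves 2 residual degrees of freedom per gene, against 4 without the block.

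Gene lists (26 lists, 274 genes by locus tag, of which 272 were measured) were fixed before the data were examined. They covered ntcA itself, nitrogen assimilation genes reported as NtcA-activated, the glutamine synthetase inactivating factors, glutamate and arginine synthesis, central carbon metabolism, the photosynthetic and respiratory complexes, ribosomal proteins, chaperones, sigma factors, pili, stress genes and the slr2030-slr2031 locus. Lists with at least 3 measured genes, 23 in all, were tested with camera in limma at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Adjusted p-values of lists are over the 23 lists. The files give locus tags and no gene names. The reference table, with 3347 genes, matched 0 of the 3074 tags, so symbols are given only for genes whose symbol and tag were fixed together in a list.

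The rule for naming genes was also fixed beforehand: ntcA; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in all 3 pairs; where none passed, the 5 with the smallest p in that direction; and, as genes that may be named, all members of the lists of ntcA, nitrogen assimilation, inactivating factors, glycogen metabolism and the slr2030-slr2031 locus and the 2 highest and 2 lowest members of each other list. Of those, 9 nitrogen assimilation genes that did not pass are given with their main difference only, and the glycogen genes (log2 -0.24 to 0.11) are not named. The fifth gene with a higher level, an unlisted tag, is left out, since at most 2 unlisted tags per direction are printed.

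On simulated data with 200 changed genes among 3074, the unpaired fit recovered 27.8% of the 2-fold and 74.3% of the 4-fold changes, and the paired fit 77.2% and 94.1%. False calls made up 4.82% and 4.63% of their calls. Each fit had its own simulated data, drawn with the residual SDs of that fit, so both fits were not compared on the same data. Noise was drawn alike for all samples, unlike in the real data, where replicate 1 stood apart. The rates may therefore not hold for the results below. With the ribosomal list raised by 0.5 log2, camera called it in 100% of 20 runs and the other lists in 0.227% of cases. The genes were simulated as independent, whereas members of real lists can vary together. These rates therefore do not give the false-call rate of the list results below.

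Alternatives covered scaling by the median or the 75th percentile, cyclic loess, loess within each same-numbered pair (span 0.3) with the block, the authors' value table, subtraction of the 1st percentile with an offset of 50, filters and floors on dim genes, each spot alone, both spots with a duplicate correlation, trended and robust eBayes, an unmoderated test and leaving out each sample or pair. Several alternatives with the block were added after seeing the data.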

Results

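The series compared the transcriptome of the glucose-tolerant wild type of the cyanobacterium Synechocystis (GT, n = 3) with that of NOX10 (n = 3), a strain that overexpresses ntcA, the gene of the global nitrogen regulator NtcA. Cells grew with ammonium, a condition of ample nitrogen, and the comparison asks which transcripts differ when ntcA is overexpressed in it. Each sample gave 6148 spot intensities. Median intensities were 415, 697 and 943 in GT replicates 1 to 3 and 510, 726 and 801 in NOX10 replicates 1 to 3. The 2 spots of a gene correlated across genes at 0.945 to 0.971 within a sample, with a median of 0.952, and the SD of their log2 difference was 0.253 to 0.505.

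The overexpressed gene ntcA (sll1423) was 6.09-fold higher in NOX10 than in GT. Its log2 level was 13.28 ± 0.68 (SD, n = 3) against 10.67 ± 0.52 (SD, n = 3), a log2 difference of 2.61 with a standard error of 0.41. Next came slr1818, 4.23-fold higher (log2 2.08, standard error 0.30), and slr2031, 2.84-fold higher (log2 1.50, standard error 0.33). In the other direction gifA (ssl1911), which encodes an inhibitory protein of glutamine synthetase, was 2.44-fold lower (log2 -1.29, standard error 0.47, and -1.68 to -0.85 with samples left out). The differences of the 3 same-numbered pairs were 2.85, 2.56 and 2.41 for ntcA, 2.05, 2.28 and 1.91 for slr1818, 1.53, 1.39 and 1.60 for slr2031, and -1.50, -1.09 and -1.27 for gifA.

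In the paired fit these were the 4 genes past the threshold, 3 of which rose and 1 of which fell. Their standard errors there were 0.13, 0.12, 0.11 and 0.13 for ntcA, slr1818, slr2031 and gifA. Their limma adjusted p was 0.00398 for ntcA, 0.0052 for slr1818, 0.0123 for slr2031 and 0.0475 for gifA. Without pair 2 the paired fit called 3 genes and gifA missed the threshold (adjusted p = 0.0569), without pair 3 it called 6, and without pair 1 it called 920, with a prior of infinite degrees of freedom. The gifA call was also lost in the paired fit after background subtraction and on the authors' value table. Without the pairing limma called 0 of 3074 genes, with 25 at an unadjusted p under 0.05, of which 6 were higher and 19 lower. The unmoderated test also called 0, with 59 at an unadjusted p under 0.05, and the fit that kept both spots apart called 2. That last fit takes both spots of a sample as separate, correlated values, so it gains precision from technical duplicates rather than from samples. The adjusted p without pairing was 0.485 for ntcA, 0.471 for slr1818 and 1.0 for slr2031 and gifA.

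**Figure D1:**
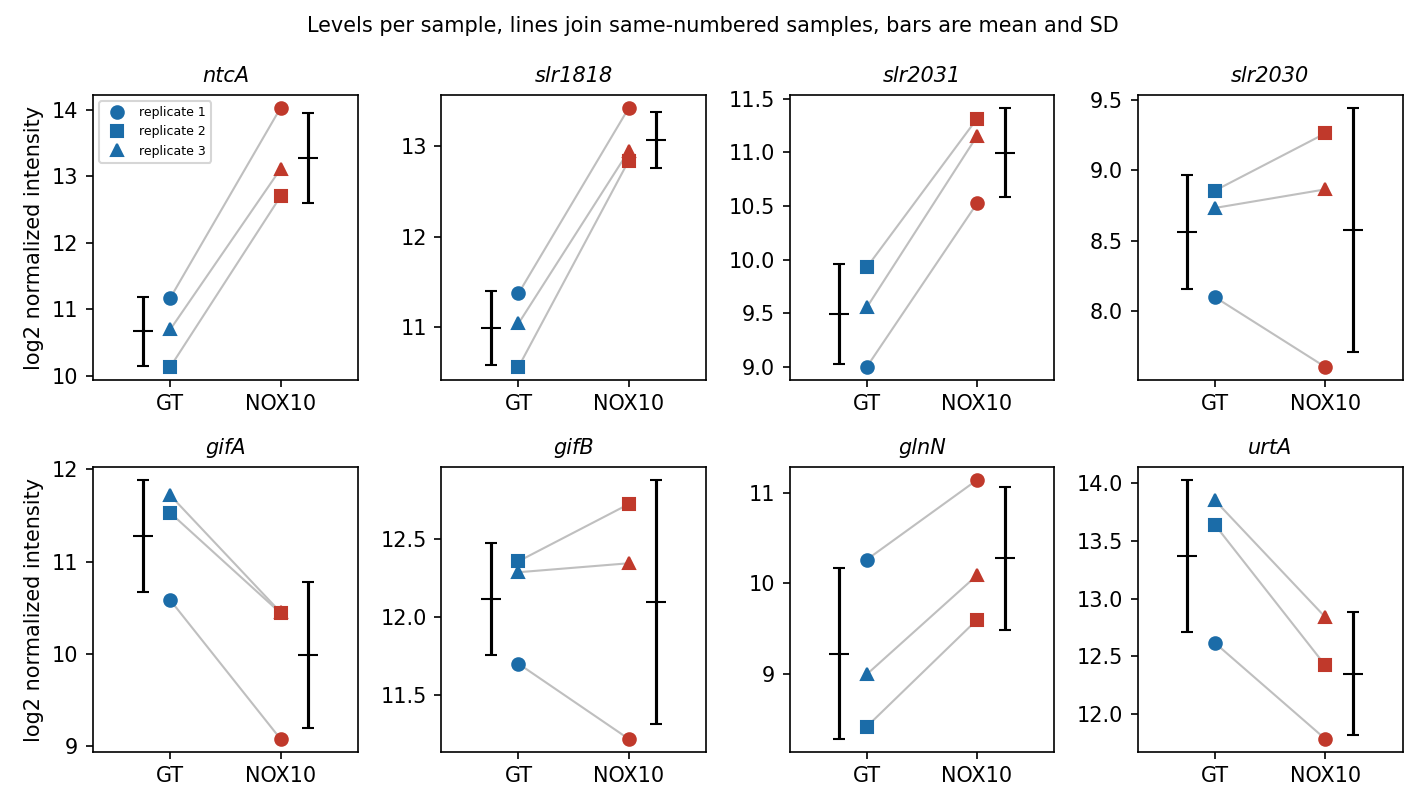
Log2 normalized intensity of 8 genes in the 3 GT (blue) and 3 NOX10 (red) samples, with same-numbered samples joined by a line and the mean and SD of each strain beside the points. All 3 lines go up for ntcA, slr1818, slr2031 and glnN and down for gifA and urtA, while those of slr2030 and gifB go both ways.

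With loess within each pair, 28 genes passed the threshold, 9 higher and 19 lower, and these included all 4 genes of the paired fit. List genes made up 10 of the 28. Among them glnN (slr0288), the type III glutamine synthetase gene, rose with a log2 difference of 1.04 and an adjusted p of 0.00546, and urtA (slr0447), the urea transporter's binding protein gene, fell by 1.01 with an adjusted p of 0.00173. The pilin gene pilA2 (sll1695) rose by 1.21 (adjusted p = 0.00841), while nrtA (sll1450), psaF (sll0819), ndhD1 (slr0331) and sigG (slr1545) fell by 0.68, 0.70, 0.62 and 0.57 (adjusted p = 0.0258, 0.0319, 0.0293 and 0.0293). These 7 genes did not pass over all genes with quantile normalization of all 6 samples, paired or unpaired, and glnN, urtA and pilA2 passed unpaired without replicate 1 (adjusted p = 0.0392, 0.0425 and 0.00539).

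The files and the reference do not pair the remaining tags with names. Among unlisted tags with the smallest p, slr0364 had a log2 difference of -2.25, with -1.04, -2.77 and -2.94 in the 3 pairs, and slr1262 one of -0.86. The tag sll1696 was higher by 0.96. None of these 3 passed in the paired fit with quantile normalization (adjusted p = 0.255 for each), and all 3 passed with loess within pairs (adjusted p = 0.00352, 0.0212 and 0.0271).

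Replicate 1 stood apart in both strains. Its samples correlated with the others at a median Spearman rho of 0.761 across genes, against 0.952 between replicates 2 and 3, and the first principal component, with 76.3% of the variance, separated them. The ratio of the 99th to the 1st percentile of intensity was 11.9 and 26.9 in replicate 1 of GT and NOX10 and 103 to 143 in the other 4 samples. Without replicate 1 the unpaired fit called 20 genes, 9 higher and 11 lower. They included the 4 genes of the paired fit, with an adjusted p of 4.16e-05 for ntcA and 0.0148 for gifA.

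**Figure D2:**
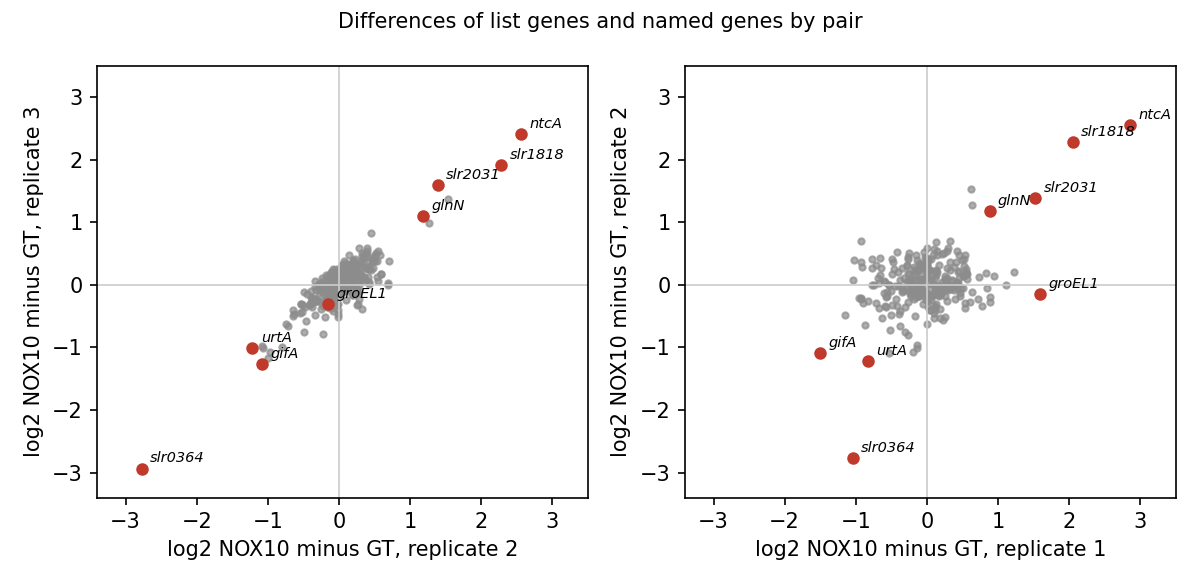
Log2 difference NOX10 minus GT of the list genes and named genes, replicate 3 against replicate 2 on the left and replicate 2 against replicate 1 on the right, with 8 genes in red. Over all genes the differences correlated at 0.775 between replicates 2 and 3 and at -0.058 between replicates 1 and 2. Between replicates 1 and 3, not shown, they correlated at 0.174.

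Among 23 nitrogen assimilation genes reported as NtcA-activated, 7 were higher and 16 lower in NOX10, with a median log2 difference of -0.18. The list fell by camera in limma (adjusted p = 0.00288, and 0.021 in the paired fit). The call was lost with adjusted p = 0.493 with an estimated correlation, and 0.617 in the paired fit. Over all genes 0 members passed in either fit. In the paired fit, adjusted over the list alone, 2 rose and 6 fell, against 0 without pairing. Those that rose were glnN (log2 1.05, standard error 0.12 in the paired fit, adjusted p over the list alone 0.0022) and icd (slr1289, isocitrate dehydrogenase, log2 0.38, 0.0485). Those that fell were urtA (log2 -1.02, standard error 0.12, 0.0022), the nitrate transporter genes nrtA (-0.79), nrtB (sll1451, -0.73), nrtC (sll1452, -0.77) and nrtD (sll1453, -0.69), and glnA (slr1756, type I glutamine synthetase, -0.51). The differences of the 3 pairs were -0.15, -0.97 and -1.08 for nrtB, -0.14, -1.005 and -1.17 for nrtC and -0.27, -0.79 and -0.999 for nrtD. In replicate 1 the raw intensities of nrtA to nrtD were 349 to 384 in GT and 251 to 411 in NOX10. They lay below the sample medians of 415 and 510. The genes nrtA to nrtD carry consecutive tags, followed by narB, so they may not be separate observations. Along with urtA, the nrt genes were the lowest of the list, and the list was not tested without them. Of the 15 members that did not pass, 5 were higher and 10 lower. Values were -0.44 for glnB (ssl0707), the gene of the PII signalling protein, and -0.32 for the nitrate reductase gene narB (sll1454). Raw intensities over the 6 samples were low, at 129 to 330.5 for glnB and 131.5 to 280.5 for narB, against sample medians of 415 to 943. For nblA2 (ssl0453), a gene of phycobilisome degradation, the value was -0.27. It was 0.34 for the ammonium transporter gene amt1 (sll0108), 0.20 for the sigma factor gene sigE (sll1689) and 0.23 for the response regulator gene rre37 (sll1330). The other urea transporter genes were at -0.24 (urtB), -0.18 (urtC), 0.17 (urtD) and -0.26 (urtE). The rest were at -0.15 (amt2), -0.17 (amt3), -0.16 (nirA), 0.26 (glsF) and -0.03 (nblA1).

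Of the inactivating factors of glutamine synthetase, both reported as NtcA-repressed, gifA fell in the paired fit over all genes and, adjusted over the list alone, with an adjusted p of 0.000123. The other factor, gifB (sll1515), had a log2 difference of -0.02, with -0.48, 0.37 and 0.06 in the 3 pairs, and 1 of 2 members thus passed. At the slr2030-slr2031 locus, a site used for inserting constructs in this species, slr2031 rose in the paired fit, adjusted over the list alone with an adjusted p of 2.4e-05. Its neighbour slr2030 had a log2 difference of 0.01 (95% confidence interval -0.45 to 0.48 in the paired fit). The labels do not say where the ntcA construct of NOX10 lies.

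Photosystem I genes were lower in NOX10 for 12 of 12 members, with a median log2 difference of -0.35, and 7 of them were lower in all 3 pairs. The list fell by camera in limma (adjusted p = 0.000323). The call was lost with adjusted p = 0.493 with an estimated correlation. Over all genes 0 members passed. In the paired fit, adjusted over the list alone, 5 fell and 0 rose, against 0 without pairing. They were the subunit genes psaJ (sml0008, log2 -0.76), psaM (smr0005, -0.65), psaF (-0.64), and psaC (ssl0563, -0.41) and psaK1 (ssr0390, -0.37), the last 2 being named after their values were seen. In replicate 1 the raw intensities of psaJ, psaM and psaC were 288, 343 and 299.5 in GT and 228, 237.5 and 226 in NOX10. Apart from psaM in GT, they lay near the 1st percentile of those samples, 240 and 181. The value of psaM in GT lay closer to the sample median of 415. The differences of the 3 pairs were -0.19, -1.07 and -1.01 for psaJ, -0.419, -0.340 and -0.475 for psaC and -0.384, -0.410 and -0.305 for psaK1. With samples left out, without pairing, psaJ lay at -1.78 to -0.12, psaC at -0.79 to -0.12 and psaK1 at -0.83 to 0.077. The direction of psaK1 turned without GT replicate 1, a fit that breaks pair 1.

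Ribosomal protein genes were higher in NOX10 for 30 of 31 members, with a median log2 difference of 0.27, and 21 of them were higher in all 3 pairs. Many of these genes carry consecutive tags, as from rpl3 (sll1799) to rpl14 (sll1806), so the members may not be separate observations. The list rose by camera in limma (adjusted p = 0.000165). The call was lost with adjusted p = 0.997 with an estimated correlation. No single member passed: 0 over all genes and 0 adjusted over the list alone, in both fits. The highest were rps2 (sll1260, log2 0.49, standard error 0.38, and 0.19 to 0.80 with samples left out) and rpl4 (sll1800, 0.46, standard error 0.25, and 0.30 to 0.58), and rps4 (slr0469) was the member with a lower level, at -0.17 (-0.32 to -0.041).

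These 3 lists were the ones called, with or without pairing, and fry called 0 of 23 lists for a shift in 1 direction. For change in either direction fry passed 5 lists in the paired fit, namely nitrogen assimilation, the NDH-1 complex and type IV pili (adjusted p = 0.017 each) and ribosomal proteins and the tricarboxylic acid cycle (adjusted p = 0.0328 each), and not photosystem I (adjusted p = 0.0521). Without pairing it passed 0 (adjusted p = 0.914 for each list). This reading of fry was added after its values were seen. Leaving out GT replicate 1 alone left 0 lists, leaving out GT replicate 3 alone gave 5, and other groupings of the 6 samples gave up to 4 without pairing and up to 5 in the paired fit. Without GT replicate 1 the adjusted p was 0.227 for nitrogen assimilation, 0.0517 for photosystem I and 0.819 for ribosomal proteins. Photosystem I also missed the threshold without NOX10 replicate 1 (adjusted p = 0.118), nitrogen assimilation without NOX10 replicate 2 (adjusted p = 0.437) and ribosomal proteins without NOX10 replicate 3 (adjusted p = 0.191). Without replicate 1 in both strains the 3 lists kept their direction (adjusted p = 0.00512 for nitrogen assimilation, 0.00651 for photosystem I and 0.00301 for ribosomal proteins). These fits with samples left out were unpaired. In the paired fit with pair 1, 2 or 3 left out, camera at the preset correlation called all 3 lists (adjusted p of 0.0374 or less).

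**Figure D3:**
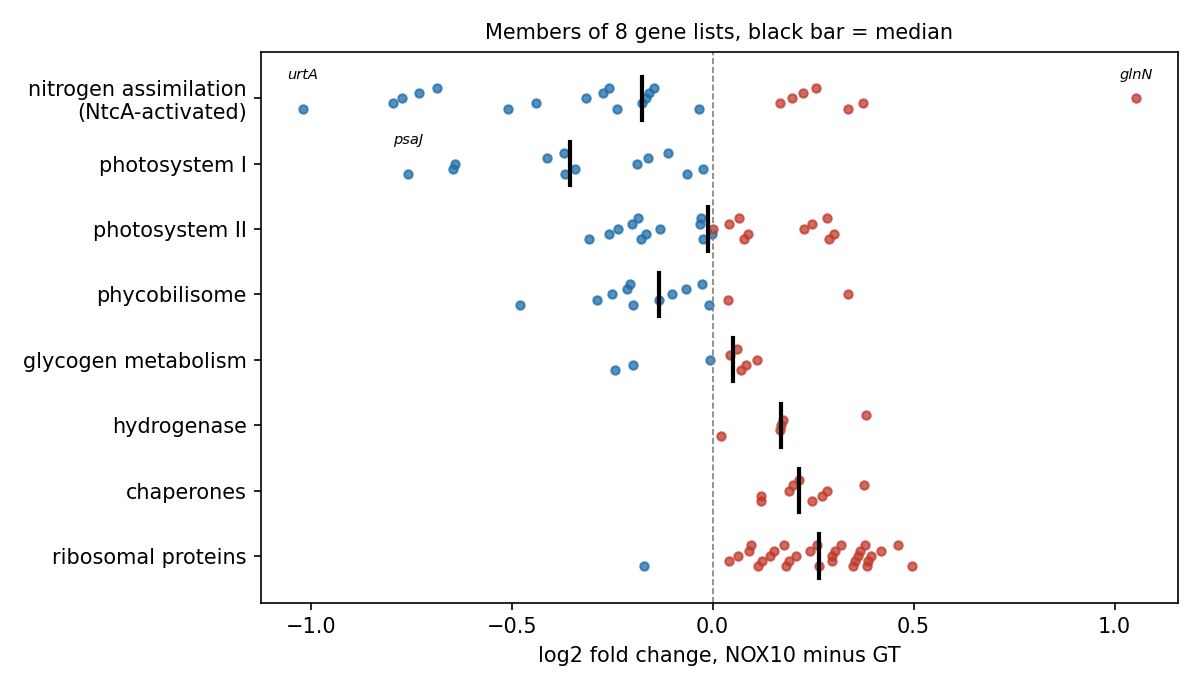
Log2 difference NOX10 minus GT of each measured member of 8 gene lists, red for higher and blue for lower in NOX10, with the list's median as a black bar. Photosystem I lies on the lower side for 12 of 12 members and ribosomal proteins on the higher side for 30 of 31.

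The other 20 tested lists did not pass (adjusted p = 0.0995 to 0.997), with mean log2 differences of -0.12 to 0.22. Members higher and lower in NOX10 numbered 5 and 3 for glycogen metabolism, 6 and 5 for glycolysis, 2 and 2 for the oxidative pentose phosphate pathway, 3 and 6 for the tricarboxylic acid cycle, 3 and 1 for polyhydroxybutyrate synthesis, and 9 and 4 for glutamate, arginine and cyanophycin synthesis. They numbered 2 and 11 for the phycobilisome, 10 and 12 for photosystem II, 5 and 7 for cytochrome b6f and soluble carriers, 2 and 6 for ATP synthase, 10 and 8 for the NDH-1 complex, and 5 and 12 for carbon fixation. For high-light inducible proteins they were 2 and 2, for sigma factors 6 and 3, for phosphate starvation genes 3 and 5, for iron stress genes 5 and 1, for type IV pili 3 and 6, and for tetrapyrrole synthesis 7 and 8. All 5 genes of the bidirectional hydrogenase and all 9 chaperone genes were higher. The median and the mean or the camera direction differed in sign for glycogen metabolism, the tricarboxylic acid cycle, cytochrome b6f, photosystem II, high-light inducible proteins and type IV pili.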

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

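Apart from loess within pairs, which was planned, alternatives that kept the replicate block while changing another choice, or that left out a pair under the block, were chosen after seeing the data. Beside 0 genes without pairing, the number called was 4 with the replicate block, 28 with loess within pairs, 2 with both spots kept apart and 0 to 20 when samples or pairs were left out. Under the block it was 920 without pair 1 (473 higher, 447 lower, with a prior of infinite degrees of freedom), 3 without pair 2, 6 without pair 3, 3 after background subtraction, 2 on the authors' value table, 9 with cyclic loess and 5 with trended and robust eBayes. The genes called under the block after background subtraction or on the authors' value table were all higher in NOX10. The fall of gifA was therefore called in neither. Over the 35 alternatives slr1818 passed in 12, slr2031 in 10 and gifA in 8. Some of the 35 changed only the list test and repeat the gene calls of the unpaired or the paired fit, so they are not all distinct. The other scalings and filters, the unmoderated test and a 2-fold minimum called 0 without pairing. The ntcA difference of 2.61 kept its direction in all 35 alternatives, at 2.26 to 2.89 when samples were left out. It passed the threshold in 12 of them, with an adjusted p from 2.46e-110 to 1.0 over the 35. These were the replicate block (2.61), loess within pairs (2.55), both spots kept apart (2.61), without replicate 1 (2.56) and, under the block, pairs 1, 2 or 3 left out (2.56, 2.61, 2.65), background subtraction (2.67), the authors' value table (2.70), cyclic loess (2.58) and trended and robust eBayes (2.61). The remaining 1 repeats the block with another list test. The lists called went from 3 to 0 with an estimated correlation, with or without the block, and with fry for a shift in 1 direction. They were 0 to 5 when samples were left out, and 5 under the block without pair 3. The means of the nitrogen assimilation, photosystem I and ribosomal lists kept their direction in all 32 alternatives, at -0.29 to -0.08, -0.48 to -0.17 and 0.02 to 0.44, and passed in 20, 27 and 27. The nitrogen list missed the threshold with scaling by the median (adjusted p = 0.0685) or the 75th percentile (adjusted p = 0.14), on the authors' value table (adjusted p = 0.145, and 0.21 with the block), with cyclic loess under the block (adjusted p = 0.0952, against 0.00743 without it), without dim genes (adjusted p = 0.139) and with a floor at the 25th percentile (adjusted p = 0.224), in a range of 0.000774 to 0.985 over its alternatives.

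Direction turned only for genes that passed over all genes neither in the paired nor in the unpaired fit. For gifB, at -0.02, it was 0.20 with scaling by the median, 0.094 by the 75th percentile, 0.010 with cyclic loess with or without the block, 0.0021 with loess within pairs, 0.12 on the authors' value table with or without the block, 0.022 on the first spot, 0.21 under the block without pair 1, and -0.33 to 0.42 when samples were left out. For slr2030, at 0.01, it was -0.036 with scaling by the median, -0.14 by the 75th percentile, -0.11 on the authors' value table and -0.062 after background subtraction, both with or without the block, -0.081 on the second spot, -0.15 and -0.011 under the block without pairs 2 and 3, and -0.32 to 0.52 when samples were left out. With samples left out, ranges were -0.045 to 0.90 for amt1, -0.12 to 0.45 for rre37, -0.013 to 0.37 for sigE, -0.83 to 0.077 for psaK1 and -0.23 to 0.73 for groEL1. Under the block without pair 1, rre37 was -0.12 and groEL1 -0.23. On the first spot narB was 0.0075 and nblA2 0.0076. Among nitrogen assimilation and photosystem I members that passed over their list alone, other ranges with samples left out were -0.90 to -0.69 for nrtA, -1.14 to -0.43 for nrtB, -1.21 to -0.52 for nrtC, -1.06 to -0.41 for nrtD, -0.76 to -0.31 for glnA, -1.39 to -0.73 for urtA, 0.64 to 1.67 for glnN, 0.18 to 0.55 for icd, -0.82 to -0.52 for psaF and -0.78 to -0.47 for psaM. With samples left out glnB lay at -0.60 to -0.13. The remaining named genes that were followed over the alternatives kept their direction. The genes glsF, urtB to urtE, nblA1, amt2, amt3 and nirA were not followed there. With quantile normalization of all samples the block changed the call of 4 genes and, by camera, of no list. With cyclic loess it ended that of the nitrogen list, and on the authors' value table it added the hydrogenase (adjusted p = 0.0374) and chaperone (adjusted p = 0.0247) lists. The causes were not tested. No file gave a background, so what lies under the lowest signals, 35 to 180 per sample, cannot be seen.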

Other observations

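The test of the gene count over splits without pairing and that of duplicate spots in replicate 1 were chosen after their values were seen, the prediction on a dye bias of single genes was written with the dyes known from the labels, and the patterns described below were chosen after seeing the data. In the paired fit, adjusted over the list alone, members of several other lists differed. In the NDH-1 complex, ATP synthase and type IV pili they did so in opposite directions. In the NDH-1 complex, which carries respiratory and cyclic electrons, ndhD2 (slr1291) rose (log2 0.51, adjusted p over the list alone 0.0296) and ndhD1 fell (-0.63, 0.0239). In ATP synthase atpE (slr1330) rose (0.44, 0.0238) and atpH (ssl2615) fell (-0.56, 0.0238). Among type IV pilus genes pilA2 rose (1.18, 0.00971) and pilN (slr1275) fell (-0.44, 0.0293), and among sigma factors sigG fell (-0.48, 0.0415). Over all genes 0 of these passed in that fit. With samples left out they lay at 0.20 to 0.88 (ndhD2), -1.08 to -0.24 (ndhD1), 0.29 to 0.59 (atpE), -0.74 to -0.28 (atpH), 0.66 to 2.01 (pilA2), -0.59 to -0.34 (pilN) and -0.76 to -0.24 (sigG).

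Some lists had different means in the 3 replicates. Chaperone genes had a mean log2 difference of 0.56 in replicate 1, 0.17 in replicate 2 and -0.06 in replicate 3, with groEL1 (slr2076) at 1.59, -0.15 and -0.31. Phycobilisome genes had means of -0.42, 0.05 and 0.0031. Hydrogenase genes had means of -0.09, 0.27 and 0.37, and that list passed without replicate 1 (camera adjusted p = 0.034). Of 32 alternatives each, the chaperone list passed in 5, the hydrogenase list in 4 and the phycobilisome list in 3. None of these 3 lists passed with quantile normalization of all samples, and the differences between replicates were not tested.

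Replicate 1 correlated less with the other replicates in both strains. A constant background on that array would leave the ranks of genes nearly intact, bright or dim. Over the brighter 50% of genes the median Spearman rho with the other replicates was 0.501, against 0.882 between replicates 2 and 3. This argues against a constant background as the whole explanation. A background that varies over the array was not tested. Noise that is random per spot would lower the agreement of duplicate spots at least as much as that between replicates. Duplicate spots within a replicate 1 sample gave a Spearman rho of 0.913 or more, against a median of 0.712 for single spots of replicate 1 with those of the other replicates (difference 0.201, 95% bootstrap interval over genes 0.182 to 0.218), which argues against it as the whole explanation, although the NOX10 minus GT differences of first and second spots correlated at only 0.461 in replicate 1, between the bounds set beforehand, and at 0.913 or more in replicates 2 and 3. An effect shared by both spots of a gene stays open, technical or biological, since the design gives no group that parts replicate 1 from the others.

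The shifts of 3 lists might come from a dye bias that depends on brightness. Among 10000 random lists of the same brightness the mean of the photosystem I list lay at percentile 0, that of the ribosomal list at 99.96 and that of the nitrogen assimilation list at 0.01. After loess within pairs they lay at 0.03, 99.96 and 0.01, which argues against such a bias as the whole explanation for all 3. The 3 lists were those already called, and the random lists draw genes without regard to shared regulation. The percentiles are therefore no second test of the shifts. A bias of single genes toward 1 dye cannot be told apart from the strain, since 0 arrays had the dyes swapped, and an effect of ntcA overexpression stays open beside it.

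Genes with consecutive locus tags, 2168 such combinations, differed alike between the strains (r = 0.28 across genes, with genes not being independent; permutation p = 1e-04, the smallest that 10000 permutations can give). Shared position on the array could do this. Differences between the first and second spot, which carry position and no RNA, correlated between consecutive tags at 0.0819 at most, under 50% of the observed value. This argues only against a position effect that differs between both spots of a gene. A position effect that both spots share cancels in these differences, so it stays open. Transcription of neighbours as 1 unit is an untested candidate explanation.

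Other splits of the samples are too few for a share under 0.05. Without pairing, the strains and each of the other 9 splits gave 0 genes, so 10 of 10 splits gave as many. Splits that set both samples of replicate 1 and 1 other sample against the rest had 490 to 646 genes at an unadjusted p under 0.05, against 25 for the strains, which points to a structure by replicate. Of the 4 splits that part all pairs, the real one gave 4 genes in the paired fit and the highest other 0, so 1 split gave as many. The others exchange the strains within 1 pair. For the lists, 4 of 10 splits gave as many as the 3 of the real one, with 4 as the highest other, and in the paired fit the highest other split gave 5 lists.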
